A study of Mus musculus with 6 samples.

How the data were processed

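Small RNA was sequenced from the renal cortex of 6 C57BL/6 mice, 3 fed a high-fat, high-cholesterol diet with bile salt for 8 weeks and 3 fed that diet with tofogliflozin for the same time. Tofogliflozin is an inhibitor of the sodium-glucose cotransporter SGLT2, which takes up glucose in the proximal tubule of the kidney. Per the labels' protocols, RNA was isolated with a NucleoSpin miRNA kit and libraries were made with a NEBNext small RNA kit for multiplexed sequencing. Per the submitters' processing notes, cutadapt 1.14 and the mouse genome build mm10 were used. The aligner, the counting program and the miRBase release are not given in the sources used here.

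The authors deposited 1 table of whole-number read counts per library, with no normalization, and every library was a separate mouse per the series' design text. Each table had 2033 rows, 1 per pairing of a mature miRNA with a precursor, and held 1900 distinct mature names. In 24 rows no mature accession was given. For 75 mature names there was more than 1 row. Rows of 47 of these names held the same values in every library, and rows of the other 28 differed. By a rule fixed before the data were examined, identical rows were counted once and differing rows were summed. From the values, reads that fit several precursors appear to be listed under each, so that summing raises miRNAs with near-identical precursors, such as miR-26a-5p and let-7f-5p. The surplus over the largest row made up 22.4% to 23.5% of each merged total. Abundances are therefore also given from the largest row alone. List names that differ between miRBase releases were matched to those in the files, miR-486a to miR-486 and miR-486b to miR-3107. Columns of other samples numbered 0.

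Total counts over all rows were 29766679, 18695091 and 19697833 in diet-only replicates 1, 2 and 3, and 18010296, 8598518 and 22628175 in tofogliflozin replicates 1, 2 and 3. A count of 0 allowed an abundance of up to 0.101 to 0.350 CPM (counts scaled to the size of the library), taking 3 counts as the limit, which covers counting error only. Reads carried no molecular identifiers in the tables, so reads are not independent molecules. Between 696 and 788 mature names had a count in a library, and 1026 had one in any library.

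Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, 2-sided, TMM factors, default filterByExpr with a smallest count of 10 and a smallest total of 15, Benjamini-Hochberg adjustment, threshold 0.05), as tofogliflozin minus diet only over all 6 libraries without covariates. The filter left 462 miRNAs and removed at most 0.00694% of the counts of a library. Standard errors (SE) are the absolute log2 fold change divided by the square root of F, and intervals are 95% intervals. Log2 CPM values used a prior count of 2. An exact 2-sided permutation test of log2 CPM stood beside single miRNAs. It has 20 arrangements, so its smallest p is 0.1.

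Of 22 miRNA lists fixed before the data were examined, 21 had at least 3 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The estimated correlation and fry were alternatives, and their use with a library left out was chosen after the data were seen. Lists cover the miR-21 locus, miRNAs described as acting on PPARα, lipid metabolism, profibrotic miRNAs, the antifibrotic miR-29 family, tubular injury, inflammation and NF-κB, hypoxia and p53, kidney tubule, epithelial miR-200, the let-7 and miR-30 families, miR-17-92 clusters and the Dlk1-Dio3 cluster. Lists of cells or tissues that a cortex sample could hold cover leukocyte, erythroid, endothelial, smooth muscle and pericyte, striated muscle, liver, neuroendocrine and ciliated epithelium. Lists share members.

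Named miRNAs were miR-21a-5p, those past the threshold (at most 10 per direction, filled up to 5 per direction with the smallest unadjusted p), the 5 most abundant, and per list up to 4 members with the smallest p, or at most 2 where the list and all its members missed the threshold. This rule named 49 miRNAs. Arm usage was tested with limma on log2 of the 5p count over the 3p count, each with a pseudocount of 1, in 75 hairpins with a mean of at least 50 counts in the lower arm. The share of counts taken by the 10 most abundant miRNAs was compared with an exact permutation test.

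Hairpin positions come from GENCODE M21, whose build GRCm38 is mm10, matched by name for 1868 of the 1900 mature names. Alternatives were other size factors, no filter or a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a robust fit, the replicate number as a block, other merging of repeated rows, other arm filters and each library left out. Sample quality weights, a factor estimated from residuals and genomic clusters were added after the data were seen.

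The tests were tested on simulated data, 20 tables per setting of 462 miRNAs drawn from the means and library sizes of this comparison. With no change, 4.81% of miRNAs had an unadjusted p under 0.05 and 0 were called. With 20 changed miRNAs per table, 7.35% of those changed 1.5-fold, 37.7% of those changed 2-fold and 90.5% of those changed 4-fold were called by edgeR. With 200 changed, these shares were 26.7%, 66.3% and 96.6%. In 1 of 20 unchanged tables a list was called by camera, and a 1.5-fold shift of the miR-17-92 list was called in 20 of 20. Each miRNA was drawn independently, while the correlation estimated for the miR-17-92 list in the data was 0.143. The simulation therefore cannot give the error rate or the power of the list test at the preset correlation in these data.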

Results

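The miRNA content of the renal cortex was compared between 3 mice fed a steatohepatitis-inducing diet and 3 mice fed that diet with the SGLT2 inhibitor tofogliflozin. Libraries held 8598518 to 29766679 counts, the fewest in tofogliflozin replicate 2. With differing rows summed, the 5 miRNAs with the highest mean CPM were miR-26a-5p, let-7f-5p, let-7c-5p, miR-10a-5p and let-7a-5p. Counted from the largest row alone, miR-26a-5p took 11.5% ± 0.522 of the counts, miR-10a-5p 8.67% ± 0.288 and let-7f-5p 8.42% ± 0.330 (SD, n = 6 libraries), and miR-192-5p, a miRNA abundant in kidney and liver, took 5.15% ± 0.272. By that count miR-10b-5p (6.45% ± 0.259) ranked 4 and miR-192-5p 5, while let-7c-5p ranked 7 and let-7a-5p was not among the first 10. The 5 with the highest mean CPM from summed rows differed little between the groups. Their log2 fold changes were 0.01 ± 0.10 (SE) for miR-26a-5p, -0.01 ± 0.10 for let-7f-5p, -0.01 ± 0.13 for let-7c-5p, 0.004 ± 0.097 for miR-10a-5p and 0.06 ± 0.11 for let-7a-5p. The values of miR-26a-5p and miR-10a-5p turned below 0 with RLE and with upper quartile size factors, among other settings.

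The first question was which miRNAs differ with tofogliflozin. No single miRNA passed the threshold in the edgeR fit with the default filter and no covariates, while DESeq2 called miR-346-5p (adjusted p = 0.0130). Highest by p among those with more counts under tofogliflozin was miR-204-5p, a miRNA of epithelia including the renal tubule, at 209 ± 16.5 CPM on the diet alone and 345 ± 52.3 CPM with tofogliflozin (SD, n = 3 each). Its log2 fold change was 0.72 ± 0.15 (SE). Its hairpin lies at chromosome 19, 22750605 to 22750672 on the plus strand of mm10, in an intron of Trpm3. miR-346-5p, from an intron of Grid1 at chromosome 14, 34894609 to 34894706, stood at 4.79 ± 1.84 CPM and 13.1 ± 2.06 CPM (SD, n = 3 each), a log2 fold change of 1.44 ± 0.30 (SE). miR-92b-3p (0.62 ± 0.16), miR-1247-5p (0.94 ± 0.27) and miR-363-3p (0.49 ± 0.17) followed. On the lower side, miR-147-3p, a miRNA induced in activated macrophages, was at 4.4 ± 1.9 CPM and 1.8 ± 0.38 CPM (SD, n = 3 each), with a log2 fold change of -1.27 ± 0.38. miR-146a-5p, a feedback inhibitor of NF-κB signalling, was at 1454 ± 474 CPM and 987 ± 55.6 CPM (SD, n = 3 each), with a log2 fold change of -0.56 ± 0.22 that was -0.27 without diet-only replicate 2. Low-abundance miR-3962 (-0.72 ± 0.28), miR-7043-3p (-0.73 ± 0.29) and miR-1191 (-0.52 ± 0.21) completed the lower side. For each of these 10 miRNAs the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 mice allow. These 10 were picked by the smallest p in these same data, so neither adds support.

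In edgeR's quasi-likelihood test, 0 of 462 miRNAs passed an adjusted p of 0.05, and the smallest adjusted p was 0.389, for miR-204-5p and miR-346-5p. At an unadjusted p under 0.05 there were 20 miRNAs, 12 higher and 8 lower, where 23.1 are expected with no effect. DESeq2 called 1, miR-346-5p (adjusted p = 0.0130), and limma-voom called 0. Groups did not overlap for 53 miRNAs (11.5%), where chance gives 10%. The median log2 fold change over all tested miRNAs was 0.03, and the biological coefficient of variation was 25.4%. Without a filter on low counts edgeR called 8, with the smallest adjusted p for miR-3535 (3.8e-07). Among the 8 were miR-346-5p (adjusted p = 6.9e-04), miR-147-3p (0.0373), miR-146a-5p (0.0487) and miR-122-5p, whose tofogliflozin mean is set by a single library. Tofogliflozin replicate 2 stood apart from the other libraries on the first principal component, which held 51.8% of the variance, and the count at an unadjusted p under 0.05 was 74 without tofogliflozin replicate 3, 11 without diet-only replicate 2 and 13 without tofogliflozin replicate 1.

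**Figure D1:**
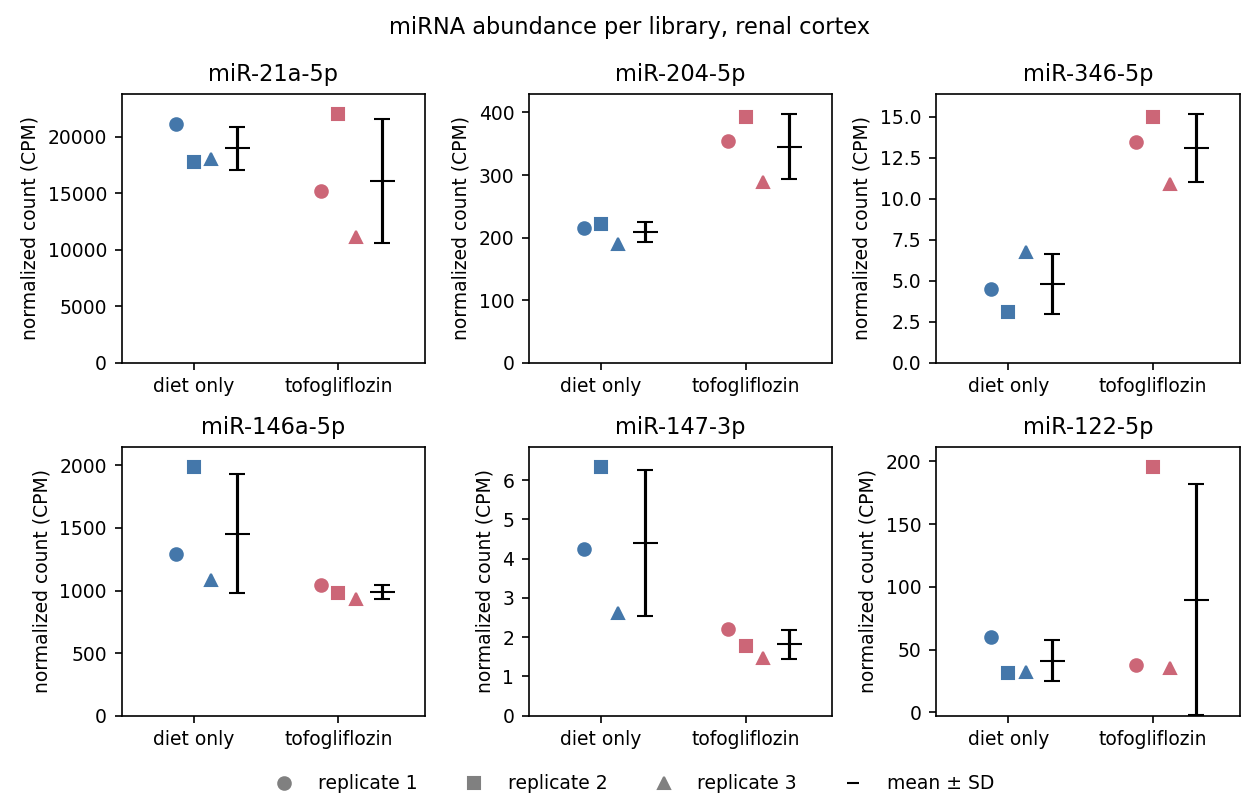
Normalized counts (CPM, linear axis) of 6 miRNAs in each library, by group, with a marker shape per replicate number and a black bar for the mean ± SD (n = 3). The groups do not overlap for miR-204-5p, miR-346-5p, miR-146a-5p and miR-147-3p, while miR-21a-5p overlaps and a single tofogliflozin library sets the mean of miR-122-5p.

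**Figure D2:**
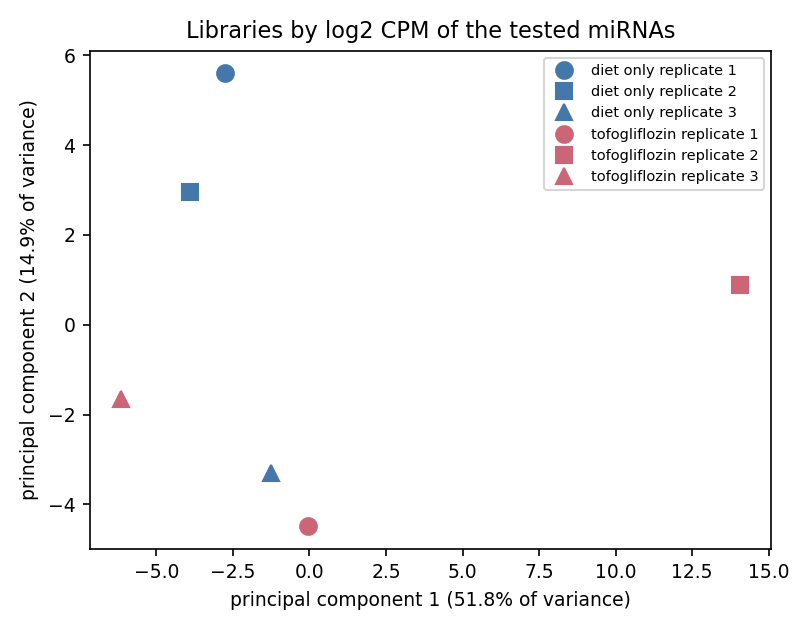
Scores of the 6 libraries on the first and second principal components of log2 CPM over the tested miRNAs, with a colour per group and a marker shape per replicate number. Tofogliflozin replicate 2 lies alone on the first component, which holds 51.8% of the variance.

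The next comparison was of miR-21a-5p, a miRNA raised in injured and fibrotic kidney and described as acting on PPARα, the lipid-oxidation regulator named in the title of the series. With differing rows summed, it was the miRNA of rank 14 by mean CPM and held 1.15% to 2.16% of the counts of a library. Summing raises the totals and so can lower such a share, as for miR-10a-5p (6.68% summed, 8.67% from the largest row). miR-21a-5p was at 18963 ± 1887 CPM on the diet alone and 16122 ± 5494 CPM with tofogliflozin (SD, n = 3 each). Its log2 fold change was -0.23 ± 0.23 (SE), with an interval of -0.77 to 0.30, so a fold between 0.585 and 1.24 was not excluded. The difference was not distinguishable from 0 in edgeR's quasi-likelihood test (p = 0.343, adjusted p = 0.876) or in the exact permutation test (p = 0.5). Its hairpin is at chromosome 11, 86584067 to 86584158 on the minus strand of mm10, within an annotated exon of Vmp1. Of the 4 tested miRNAs of the miR-21 name, 3 had a log2 fold change below 0 (median -0.23, camera adjusted p = 0.50). miR-21c was at -0.22 ± 0.25, and its reads cannot be separated with certainty from those of miR-21a, since the mature sequences are nearly the same. Without tofogliflozin replicate 2, the log2 fold change of miR-21a-5p was -0.55 (adjusted p = 0.535 by edgeR) and the list passed the threshold at the preset correlation (median -0.54, adjusted p = 0.00388), but not with an estimated correlation (adjusted p = 0.871) or with fry (adjusted p = 0.104). Without tofogliflozin replicate 3, miR-21a-5p was at -0.05. For miR-21c these values were -0.53 and -0.03.

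Lists of miRNAs that belong together were compared next. Members of the miR-17-92 clusters, a set of proliferation-associated miRNAs, were higher with tofogliflozin as a list at camera's preset correlation only. Of 13 tested members, 10 had a log2 fold change above 0, 3 of them at an unadjusted p under 0.05 and 0 past the threshold alone, and the median was 0.41 (mean 0.33, camera adjusted p = 0.0434). The call was lost with an estimated correlation (adjusted p = 0.969) and with fry (adjusted p = 0.916). miR-92a-3p was at 1780 ± 123 CPM and 2192 ± 177 CPM (SD, n = 3 each), a log2 fold change of 0.30 ± 0.11, and miR-363-3p was at 14.2 ± 1.87 CPM and 19.98 ± 0.524 CPM. miR-20b-5p (0.73 ± 0.30) and miR-106a-5p (0.84 ± 0.37) share most of their sequence with miR-17-5p (0.61 ± 0.30), so that reads can pass between them. Without tofogliflozin replicate 2 these 3 were at 0.36, 0.37 and 0.23. The list's call was also lost without tofogliflozin replicate 2 (median 0.18, adjusted p = 0.0775) and without diet-only replicate 1, diet-only replicate 2 or tofogliflozin replicate 1 (adjusted p = 0.156, 0.0551 and 0.160), with no low-count filter and with the replicate number as a block.

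**Figure D3:**
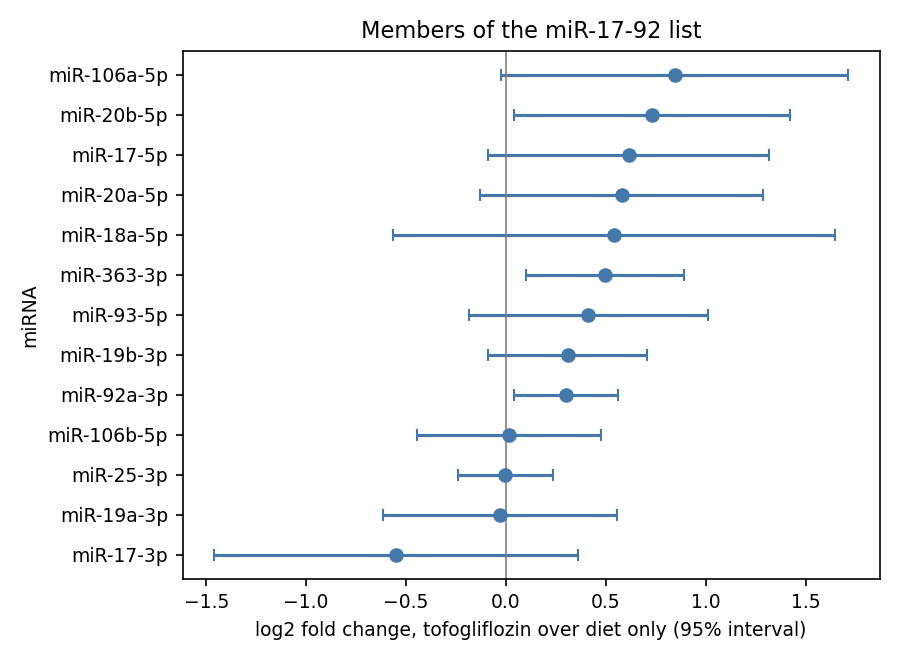
Log2 fold change of each of the 13 tested members of the miR-17-92 clusters, tofogliflozin over diet only, from edgeR, with 95% intervals over 3 mice per group. Of these, 10 lie above 0, and 3 of the intervals exclude 0.

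The medians of the inflammation, PPARα, profibrotic, hypoxia and p53, kidney tubule, miR-200, let-7, miR-30, endothelial, neuroendocrine, striated muscle and ciliated epithelium lists changed sign with at least 1 library left out. In the leukocyte list, 8 of 11 members were below 0, with a median of -0.15 (adjusted p = 0.367 by camera), which was -0.54 without tofogliflozin replicate 2 (adjusted p = 0.0775) and -0.03 without tofogliflozin replicate 3 or diet-only replicate 2 and -0.05 without tofogliflozin replicate 1. Its members included both miR-146a-5p and miR-147-3p below 0 and miR-181b-5p at 0.36 ± 0.13 (0.24 without diet-only replicate 1). The inflammation and NF-κB list was at a median of -0.02 with 6 members on either side (adjusted p = 0.843). Tubular injury miRNAs had 9 of 11 members below 0 and a median of -0.10 (adjusted p = 0.367), from -0.14 without diet-only replicate 2 to -0.07 without diet-only replicate 1, miR-146a-5p and miR-21a-5p among them. These 3 lists share miR-146a-5p and so are not independent of each other.

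For lipid handling and PPARα, no shift was detectable. Of 12 miRNAs described as acting on PPARα, 7 were above 0 and 5 below, with a median of 0.07 (camera adjusted p = 0.901), led by miR-20b-5p and miR-17-5p. The 18 tested miRNAs of lipid metabolism were split 9 and 9 (median -0.01, mean 0.04, adjusted p = 0.680), with a median down to -0.09 with a library left out (tofogliflozin replicate 3). Among them miR-183-5p, from a cluster on chromosome 6, was at 177 ± 16.1 CPM and 129 ± 32.3 CPM (SD, n = 3 each), a log2 fold change of -0.46 ± 0.20 (-0.69 without tofogliflozin replicate 2), and miR-370-3p was at 0.75 ± 0.38 (0.32 without tofogliflozin replicate 1).

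Fibrosis lists did not pass the threshold. Profibrotic miRNAs had a median of 0.08 over 15 members (adjusted p = 0.901), with miR-382-5p at -0.76 ± 0.40 and miR-212-3p at 0.69 ± 0.40. In the miR-29 family, which represses collagen genes, the median was -0.08 and the mean 0.0003 over 6 members (adjusted p = 0.901), with miR-29c-5p at -0.58 ± 0.24 and miR-29b-1-5p at 0.82 ± 0.46. The list holds both 5p and 3p arms, with 3 members above 0 and 3 below. Of the 3p arms, miR-29c-3p was at -0.24 ± 0.25 and miR-29a-3p at -0.18 ± 0.22, both among those below 0. The miR-29 median ran from -0.34 without tofogliflozin replicate 3 to -0.02 without tofogliflozin replicate 2. Hypoxia and p53 miRNAs had a median of 0.04 over 9 members (adjusted p = 0.972). Of these miR-210-3p was at 0.55 ± 0.46, and at -0.09 without tofogliflozin replicate 2.

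Kidney tubule miRNAs had 7 of 12 members above 0 and a median of 0.02 (camera adjusted p = 0.901). One of them, miR-204-5p, passed when adjusted over the list alone (adjusted p = 0.0177), the single miRNA of any list to do so, against 0 over all miRNAs tested. miR-30c-5p (0.24 ± 0.21), miR-30a-5p (0.22 ± 0.22) and miR-196b-5p (0.13 ± 0.11) were other members, and both miR-30 values turned below 0 without tofogliflozin replicate 2 (-0.02 and -0.08). The miR-30 family had a median of 0.03 and a mean of 0.05, while camera's direction was down (adjusted p = 0.901), with miR-30d-3p at -0.26 ± 0.19 (-0.41 without diet-only replicate 1). The epithelial miR-200 list had a median of -0.10 and a mean of 0.02 over 9 members (adjusted p = 0.901), with miR-200c-3p at 0.35 ± 0.17 and miR-200a-5p at -0.22 ± 0.12. For the let-7 family the median was 0.004, the mean -0.002 and the adjusted p 0.901, with let-7d-5p at 0.12 ± 0.10 and let-7k at -0.22 ± 0.18 (-0.33 without diet-only replicate 2). In the imprinted Dlk1-Dio3 cluster of chromosome 12, 9 of 14 members were above 0 with a median of 0.27 (adjusted p = 0.367), which was 0.07 without diet-only replicate 2.

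Markers of other cells and tissues were compared to see what else the cortex samples held. Erythroid miRNAs had 4 of 5 members above 0 and a median of 0.49 (camera adjusted p = 0.340), which was 0.23 without tofogliflozin replicate 2 and 0.34 without diet-only replicate 1. The list passed without diet-only replicate 3 at the preset correlation (median 0.79, adjusted p = 0.0291), but not with an estimated correlation (adjusted p = 0.808). miR-3107-5p, which lies opposite miR-486 and cannot be separated from it, was at 71.4 ± 45.9 CPM and 117 ± 59.8 CPM (SD, n = 3 each), a log2 fold change of 0.71 ± 0.52 that ran from 0.23 without tofogliflozin replicate 2 to 1.33 without diet-only replicate 3. miR-363-3p belongs to this list and to the miR-17-92 list. The hepatocyte miRNA miR-122-5p, the 1 tested member of the liver list, was at 41.0 ± 16.4 CPM and 89.7 ± 91.9 CPM (SD, n = 3 each), a log2 fold change of 1.12 ± 0.67 that became -0.19 without tofogliflozin replicate 2. Endothelial miRNAs had a median of -0.04 (adjusted p = 0.901), with miR-126a-3p at -0.11 ± 0.14 and miR-139-5p at 0.17 ± 0.16. Smooth muscle and pericyte miRNAs were at 0.10 (adjusted p = 0.901), with a median from 0.02 without tofogliflozin replicate 2 to 0.22 without tofogliflozin replicate 1, with miR-143-5p at 0.28 ± 0.18 and miR-145a-5p at 0.21 ± 0.14. Neuroendocrine miRNAs were at 0.14 (adjusted p = 0.901), with miR-129-5p at -0.34 ± 0.15 and miR-7b-5p at 0.65 ± 0.38. Striated muscle was at 0.01 (adjusted p = 0.951; miR-206-3p 0.29 ± 0.36, miR-499-5p -0.16 ± 0.48) and ciliated epithelium at -0.07 (adjusted p = 0.901; miR-34c-5p 0.19 ± 0.18, miR-34c-3p -0.27 ± 0.47), with 3 tested members each. Other log2 fold changes also fell without tofogliflozin replicate 2, to 0.32 for miR-29b-1-5p, 0.22 for miR-7b-5p, 0.12 for miR-200c-3p and miR-143-5p, 0.06 for miR-145a-5p and miR-196b-5p and 0.02 for miR-139-5p, and miR-126a-3p went to -0.03 (-0.24 without tofogliflozin replicate 3). For miR-206-3p the value was 0.14 without tofogliflozin replicate 1, for let-7d-5p 0.04 without diet-only replicate 3, and for miR-34c-3p -0.01 without diet-only replicate 2 and -0.62 without tofogliflozin replicate 1.

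Whether the arms of a hairpin were used differently was tested in 75 hairpins with limma. None passed the threshold (smallest adjusted p = 0.932), and 1, miR-486, had an unadjusted p under 0.05, with the log2 ratio of 5p to 3p higher by 0.90 ± 0.39 (SE) with tofogliflozin. The 10 most abundant miRNAs together took 68.2% ± 0.916 of the counts on the diet alone and 68.0% ± 1.72 with tofogliflozin (SD, n = 3 each; exact permutation p = 0.8). Counted from the largest row, these shares were 62.6% ± 0.582 and 62.0% ± 1.96 (SD, n = 3 each; exact permutation p = 0.9).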

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

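Sample quality weights, the residual factor, genomic clusters and the list tests with both a library left out and an estimated correlation or fry were chosen after seeing the data, and the other alternatives before. MiR-21a-5p kept its direction and stayed short of the threshold under every alternative run, from -0.55 to -0.05, both ends with a library left out. The count of called miRNAs stayed 0 except with no low-count filter (8 of 1026), DESeq2 (1) and a residual factor (12). Both without the filter and with the residual factor, miR-346-5p, miR-1291 and miR-3535 were called. Arm usage gave 0 calls under each alternative. Of 915 values of named miRNAs under alternatives, 35 reversed and 9 passed the threshold; of 270 list values, 43 reversed and 7 passed. The cause was not tested unless given here. The number of called lists fell from 1 to 0 with an estimated correlation, fry, no low-count filter and the replicate block, and ran from 0 to 2 with a library left out, but was 0 in each of these with an estimated correlation or fry. The miR-17-92 median was 0.41 with an estimated correlation and fry, 0.29 with no low-count filter and 0.35 with the block, and 0.18 to 0.46 with a library left out. Same-numbered mice did not deviate together (r = -0.02, -0.11 and -0.17 across miRNAs), and no library correlated best with its own number. With so few libraries these values show no sign of a pairing but cannot exclude one. With the replicate number as a block, 0 miRNAs were called, as without it, and 9 had an unadjusted p under 0.05. That count was 61 with no low-count filter, 12 with the 10 CPM filter, 37 with quality weights and 87 with the residual factor.

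Results within about 0.1 of 0 account for most reversals. With RLE size factors miR-26a-5p was at -0.013, miR-10a-5p at -0.020, let-7 at -0.020 and striated muscle at -0.0042. Upper quartile factors gave -0.022 and -0.032 for miR-26a-5p and miR-10a-5p, DESeq2 -0.016 and -0.023, the largest repeated row -0.025 and -0.032, and the sum of rows -0.011 and -0.017. No low-count filter gave let-7a-5p -0.0037, miR-26a-5p -0.047, miR-10a-5p -0.054, kidney tubule -0.011, let-7 -0.057, miR-30 -0.034 and hypoxia and p53 -0.011. The 10 CPM filter gave miR-26a-5p -0.0011, miR-10a-5p -0.0082, inflammation 0.014, kidney tubule -0.0082, smooth muscle -0.026, let-7 -0.016, profibrotic -0.025 and PPARα -0.072. Let-7 was at -2.1e-05 with total counts and -0.0012 with the block. Quality weights gave miR-34c-3p 0.041 and let-7f-5p 0.028. The composition difference was 0.092 percentage points for the top 1 and 0.16 for the top 5.

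With a library left out, composition ran from -0.76 to 0.77 points. Single miRNAs ran from -0.053 to 0.11 (let-7a-5p), -0.13 to 0.070 (let-7c-5p), -0.083 to 0.024 (let-7f-5p), -0.062 to 0.059 (miR-10a-5p) and -0.051 to 0.040 (miR-26a-5p). Without tofogliflozin replicate 2 signs turned for miR-122-5p (-0.19 to 1.49), miR-210-3p (-0.088 to 0.90), miR-30a-5p (-0.085 to 0.39), miR-30c-5p (-0.017 to 0.40), miR-34c-5p (-0.013 to 0.28) and miR-499-5p (-0.71 to 0.17). List medians ran from -0.038 to 0.11 (PPARα), -0.20 to 0.13 (ciliated), -0.20 to 0.030 (endothelial), -0.15 to 0.021 (miR-200), -0.087 to 0.25 (hypoxia and p53), -0.14 to 0.19 (inflammation), -0.027 to 0.091 (kidney tubule), -0.062 to 0.051 (let-7), -0.053 to 0.079 (miR-30), -0.10 to 0.15 (neuroendocrine), -0.080 to 0.18 (profibrotic) and -0.0093 to 0.21 (striated muscle). Depth limits miRNAs of a few CPM most, since tofogliflozin replicate 2 held 8598518 counts.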

Other observations

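The tests of this part, clusters included, were chosen after the results were seen. Hairpins that lie within 10 kb of each other on 1 strand were grouped into 33 clusters, and the mean log2 CPM of each was compared with limma. None passed the threshold (smallest adjusted p = 0.30), and 3 had an unadjusted p under 0.05. Mir363, Mir20b and Mir106a, at chromosome X, 52741693 to 52742567, were higher with tofogliflozin by 0.50 ± 0.16 (SE) with 4 of 4 arms above 0, and by 0.32 without tofogliflozin replicate 2. The cluster of Mir17, Mir18, Mir19a and Mir20a, with arms in the same miRNA list, differed by 0.15 ± 0.17, and by 0.01 without tofogliflozin replicate 2. Over all libraries its arms did not move together. Those of miR-17-5p, miR-20a-5p, miR-18a-5p and miR-18a-3p were at 0.61, 0.58, 0.54 and 0.28, miR-19a-3p at -0.03 and miR-17-3p at -0.55. The cluster of Mir25, Mir93 and Mir106b, also with arms in that list, differed by 0.07 ± 0.17, and by -0.06 without tofogliflozin replicate 2. Mir181d and Mir181c, at chromosome 8, 84178716 to 84178961, were higher by 0.28 ± 0.11, with 3 of 3 arms above 0. The cluster of Mir29b-2 and Mir29c, at chromosome 1, 195037040 to 195037634, differed by -0.30 ± 0.09, mainly through miR-29c-5p, with 1 of 3 arms above 0. Mir182, Mir96 and Mir183, expressed in sensory and other epithelia, differed by -0.44 ± 0.28, and by -0.78 without tofogliflozin replicate 2 (adjusted p = 0.269 by limma). Without diet-only replicate 3, 34 clusters were tested and 1 passed, Mir193b with Mir365-1, at -1.10 ± 0.17 (adjusted p = 0.0138). It is not among the 33, since no arm of Mir193b passed the low-count filter over all 6 libraries, where miR-365-1-5p was at -0.57 ± 0.63.

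Tofogliflozin replicate 2 stood apart, at a median distance of 0.861 log2 units from the other libraries, against 0.526 to 0.561 for the rest. A change in hairpin transcription moves both arms of a hairpin. The log2 arm ratios of tofogliflozin replicate 2 deviated from the mean of the other libraries with an SD of 0.862 over hairpins. For each other library, against the rest without tofogliflozin replicate 2, this SD was at most 0.462. In tofogliflozin replicate 2 the 5p and 3p deviations were uncorrelated over 75 hairpins (r = -0.046, upper bootstrap bound 0.152). The spread of these ratio deviations argues against transcription as the whole cause. It was not taken on thinned counts, so counting error at the lower depth may add to it. Cell makeup stays open, since the hepatocyte miRNA miR-122-5p was at 7.61 log2 CPM in tofogliflozin replicate 2 and at 4.96 to 5.91 elsewhere. A low r is not particular to it, since the other libraries ran from -0.035 to 0.535. Lower depth alone is argued against as well: fewer reads lower the chi-square per degree of freedom of a pair of libraries, but its 5 pairs had 708 to 1692 and the other 10 pairs 115 to 516, a lowest-to-highest ratio of 1.37. With every library thinned to its total, its distance was 1.31 to 1.44 times the next highest in 10 thinnings. This ratio was the first test and fell between the bounds set for it, so it left depth undecided, and the chi-square replaced it after the values were seen. An effect of the mature sequence on yield or decay may contribute and also cannot be settled, since same-arm family members deviated together (r = 0.51) no more than in the other libraries (up to 0.592), and shared reads would give the same. Treatment is shared with 2 mice that do not show the pattern, and no other biological explanation was tested.

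The higher miR-17-92 list may rest on that library: without it the median was 0.18 with an unadjusted camera p of 0.0161, but 0.306 with an estimated correlation, which does not settle it. Blood in the tissue is another candidate explanation. With the mean of miR-451a, miR-486-5p and miR-3107-5p as a covariate, the group difference of the list mean went from 0.27 to 0.17 ± 0.14 (SE). Blood and treatment therefore cannot be told apart with 6 libraries. miR-486-5p and miR-3107-5p cannot be separated from each other, so that they weigh more than miR-451a in the covariate. In the diet-only libraries the marker mean ran from 3.87 to 5.70 log2 CPM while the list mean stayed at 4.34 to 4.4. In the tofogliflozin libraries both were lowest in replicate 3 (markers 4.82, list 4.37), higher in replicate 1 (5.63 and 4.68) and highest in replicate 2 (6.03 and 4.84), and the list mean of replicate 3 lay within the diet-only range.

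For miR-204-5p, tofogliflozin replicate 2 alone is argued against by a log2 fold change of 0.60 ± 0.14 (SE) without it (adjusted p = 0.357 by edgeR). That value cannot test chance, since miR-204-5p was picked by the smallest p in these same libraries. Chance stays open, with an adjusted p of 0.389 by edgeR over all libraries. Reads shared with miR-211-5p are argued against by its counts, 0.0752% of those of miR-204-5p. Transcription of the hairpin stays open, since the 3p arm was at 0.26 ± 0.27, with an interval reaching 0.89. The treatment, which the design names, stays among the open explanations without a further test.

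The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For called miRNAs, arm usage and clusters the real split and each other split gave 0, so 10 of 10 were as large. The real split gave 20 miRNAs at an unadjusted p under 0.05, the highest other 58, and 4 splits gave as many. It gave 1 list, the highest other 2, and 6 splits gave as many. With the residual factor it gave 12 calls and the highest other 57, and 3 splits gave as many. The split with 58 and 57 put diet-only replicates 1 and 2 with tofogliflozin replicate 3. It was singled out as the highest of 10, had 0 called miRNAs without the residual factor and cuts the libraries along the first principal component (scores of -2.74, -3.89 and -6.16 against -1.25, -0.04 and 14.08), so it restates that spread and shows no cause for it. It also parts the libraries by the mean of the erythroid markers, at 3.87, 4.84 and 4.82 log2 CPM against 5.70, 5.63 and 6.03.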
